A study of Glycine max with 4 samples.

How the data were processed

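ChIP-seq was performed on early maturation embryos of soybean, with 2 ChIP samples and 2 input samples. Per the labels' protocols, the tissue was crosslinked in 1% formaldehyde for 10 minutes, chromatin was sonicated to fragments of 100 to 500 bp, and 2 µg of the anti-peptide antibody was used. Libraries were amplified with 15 cycles of PCR. Reads were aligned with Bowtie 0.12.7 and MACS2 was used, per the submitters' processing notes. The genome assembly and the MACS2 version are not given in the sources used here. Samples were grouped as ChIP or input by their titles, which also give the replicate number.

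The deposited data analysed here are a peak list for each ChIP replicate, so peaks were called per replicate and not on pooled samples. The inputs enter only through the authors' peak calling, and ChIP was compared with input only through the pileups and backgrounds recovered from the peaks. The authors deposited 4 values for each peak, in the column order of the MACS2 narrowPeak format. The fold is a linear ratio of ChIP to the background of the peak caller at the summit, per that column order. The deposited significance values are −log10 of the p-value and of the q-value. The deposited score equals the whole part of 10 times the −log10 q in 99.997% of the peaks of replicate 1 and 99.96% of those of replicate 2. A further column gives the position of the summit within the peak. The peak names of replicate 2 contain a q of 0.01, and those of replicate 1 name no threshold. The lowest −log10 q in both lists lies above 2, so the same threshold is compatible with both. Peak names of both lists contain the letters P1, and those of replicate 2 also contain lib3. The labels call the samples biological replicates and do not explain these letters, so whether they came from separate plants is not settled and the spread between them may in part be technical.

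Read totals were not given, and the depth was recovered from the peaks. For each peak, the whole number of ChIP fragments k and the background λ were found for which (k + 1)/(λ + 1) equals the deposited fold and the upper Poisson tail above k equals the deposited p-value. In 5000 simulated peaks with backgrounds of 2.3 to 9, all pileups were recovered (100%), and of 4619 simulated peaks with pileups that were not whole none (0%) passed as whole. On the deposited peaks the largest deviation was 0.072% of a step in replicate 1 and 0.58% in replicate 2. Above the genome-wide floor, the recovered backgrounds were whole numbers of input reads in a window of 1 fragment length, 1 kb or 10 kb, times 1 scale per replicate, in 100% of the peaks of replicate 1 and 99.8% of replicate 2. The scale was 0.880 in replicate 1 and 0.497 in replicate 2. The tolerance was 0.002 reads for the fragment window, 0.01 for 1 kb and 0.05 for 10 kb. ChIP pileups were unscaled and the input was scaled down to the ChIP. The fragment length was taken as the smallest peak width, which 820 peaks of replicate 1 and 983 peaks of replicate 2 share. These depths rest on how MACS2 is known to compute its values and are not read totals. PCR duplicates without molecular identifiers are not independent molecules, so exact Poisson intervals (95%) of pileups and Wilson intervals (95%) of shares cover counting error only.

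Peaks overlapping by at least 1 bp counted as found in both replicates. Shared sites are one-to-one pairs of overlapping peaks, joined in order of summit distance, at the midpoint of the 2 summits. The overlap was tested against 1000 random placements of the peaks within their chromosomes, keeping widths. Densities in the outer and inner parts of chromosomes were compared by a paired sign-flip permutation test with 100000 resamples, and neighbours within 2 kb against 1000 placements within 500 kb. Values of 2 replicates are given as mean ± SD with n = 2. The named sites are the 20 shared sites with the highest lower-of-2 fold, which is the ranking fixed for bound genes before the data were examined, applied to sites. The comparison of chromosome parts, the neighbour test and the depth recovery were added after the data were examined. The densest windows, longest runs and single discordant sites were chosen after their values were seen. The methods were tested on simulated data: 31085 randomly placed peaks differed from the expected overlap by −0.05 percentage points, and 30% of planted copies raised it by 29.3 points. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

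A total of 5 planned results were not run, namely the location of peaks relative to genes, a test of 28 fixed motifs, a test of all 6-mers, the bound genes and a test of 42 fixed gene lists. They need the genome or annotation of the assembly used by the authors. The gene table at hand belongs to the assembly Glycine_max_v4.0, carries 0 GLYMA identifiers and ends before the last peak on 5 of the 20 chromosomes, so it was not used to place peaks or to name the assayed gene. Alternatives fixed before the data were examined were a −log10 q of at least 10, the 5000 peaks of highest −log10 q, reciprocal overlap of 50%, summits within 100 bp, and −log10 q in place of fold. The alternatives chosen after seeing the data were placement within 500 kb, removal of peaks with a background over 20, the outer 10% at each end, and the density and neighbour results under all settings.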

Results

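The binding sites of the protein encoded by GLYMA.07G038400 were mapped in soybean embryos by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is recovered with an antibody and sequenced. The embryos came from the cultivar Williams 82 and were at the early maturation stage, when storage reserves begin to accumulate. They were dissected from seeds 6 to 7 mm long. The antibody was raised against a peptide covering amino acids 188 to 202 of the protein. The names of the deposited peaks carry the abbreviation GRF5, which the labels do not spell out. In plants GRF is the usual abbreviation of growth-regulating factor, a family of transcription factors. The series holds 4 samples, namely 2 ChIP replicates described as biological and an input (total chromatin) control for each. The question was where in the genome the protein was bound, and the replicates show how well each site was recovered a second time.

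Peaks, referred to as sites, were called at 31090 positions in replicate 1 and at 25502 in replicate 2. The only controls were inputs, so sites that the antibody recovers without the protein cannot be told from bound ones. Sites were narrow, with a median width of 386 bp in replicate 1 and 319 bp in replicate 2, and together they covered 13.5 Mb and 9.15 Mb of the genome. The median fold enrichment over background was 6.37 (interquartile range 4.69 to 9.87) in replicate 1 and 6.49 (4.99 to 9.68) in replicate 2. A fold enrichment above 20 was reached by 1658 sites in replicate 1 and by 1155 in replicate 2, and the highest values were 76.2 and 62.1. The weakest site kept had a −log10 q of 2.05 in replicate 1 and of 2.16 in replicate 2. Fold enrichment, p and q are the authors' values for each peak.

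The read depth behind each site was recovered from the peak values themselves. In every peak of both lists the fold enrichment and the p-value were met by a whole number of ChIP fragments at the summit and a Poisson background, within 1% of the step between neighbouring whole numbers. The median site rested on 34 overlapping fragments in replicate 1 (minimum 12) and on 26 in replicate 2 (minimum 11). The lowest background, which the peak caller sets from the genome-wide mean, was 3.11 fragments in replicate 1 and 2.31 in replicate 2. With fragment lengths of 222 and 191 bp, taken from the smallest peak width of each list, this corresponds to 14.02 and 12.07 retained ChIP reads per kb of the genome size used in calling. The input held 1.14 times the reads of the ChIP in replicate 1 and 2.01 times in replicate 2. Intervals given for these pileups cover counting error only.

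**Figure D1:**
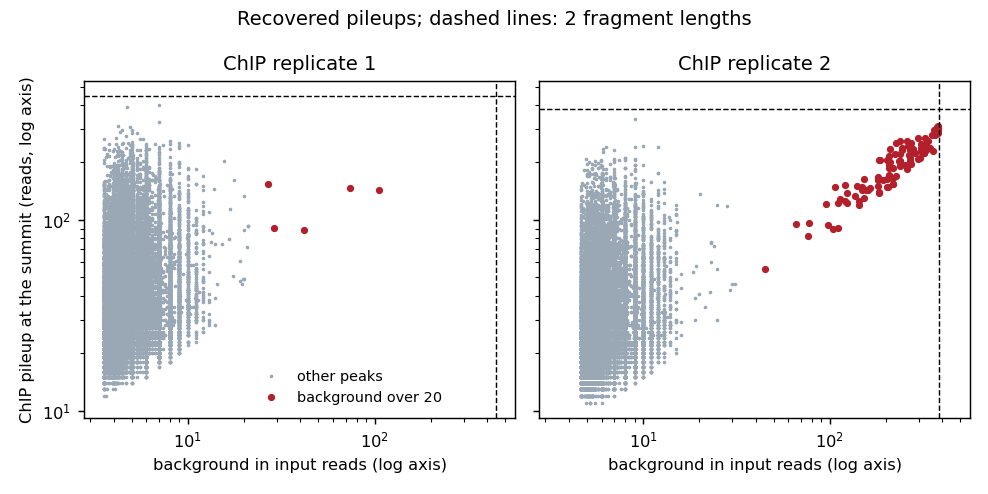
ChIP pileup at the summit (y axis, fragments) against the background expressed in input reads (x axis) for each peak of ChIP replicate 1 (left) and replicate 2 (right), both on log axes; red points have a background over 20 and dashed lines mark 2 fragment lengths. Red points number 5 in replicate 1 and 106 in replicate 2.

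Most sites were found in both replicates. Of the replicate 1 peaks, 22386 (72.0%, 95% Wilson interval 71.5 to 72.5) overlapped a replicate 2 peak by at least 1 bp. Of the replicate 2 peaks, 22906 (89.8%, 89.4 to 90.2) overlapped a replicate 1 peak. When the replicate 1 peaks were placed at random on their chromosomes 1000 times, 2.19% overlapped on average and at most 2.44% did (one-sided permutation test, p = 0.001, the smallest these placements can give). Permutation of the peaks within 500 kb of their own positions, which keeps regional density, gave 4.00% on average and at most 4.34%, again with p = 0.001. One-to-one pairing of overlapping peaks left 22364 shared sites. Their summits lay a median of 30 bp apart (interquartile range 14 to 56 bp), and 92.1% lay within 100 bp.

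Recovery in the other replicate depended on the strength of the site. In the weakest decile of replicate 1, with folds of up to 3.89, 35.2% of the sites (33.6 to 36.9) had a counterpart in replicate 2. This share was 69.1% in the fifth decile, 98.5% in the eighth and 99.97% in the strongest, where 3108 of 3109 sites with folds of at least 15.6 were recovered. In replicate 2 the share rose from 70.4% (68.6 to 72.2) in the weakest decile to 100% of 2548 sites in the strongest. The 8704 replicate 1 sites without a counterpart had a median fold of 4.59, and those with one had a median of 7.90. Only 10 of the 7585 replicate 1 sites above 10-fold had no counterpart, and in replicate 2 it was 2 of 6013. The strongest of them were a site on chromosome 8 at 13066658 to 13067746, with 19.4-fold enrichment in replicate 1, and a site on chromosome 19 at 41949294 to 41949583, with 11.7-fold enrichment in replicate 2.

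**Figure D2:**
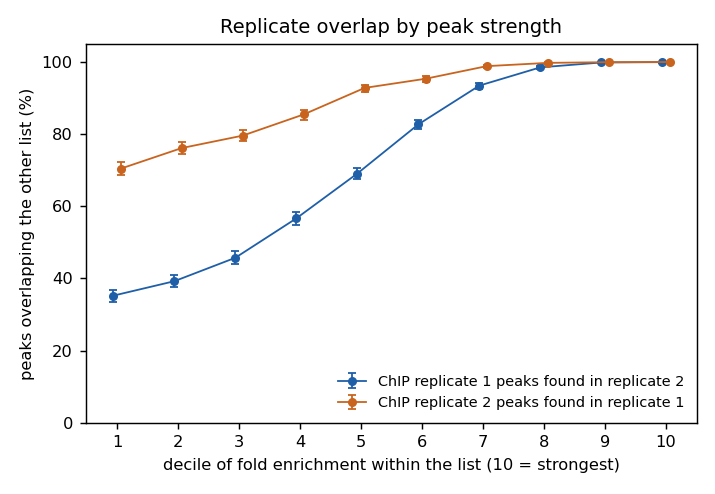
Share of peaks overlapping a peak of the other ChIP replicate (y axis, percent) by decile of fold enrichment within each list (x axis); bars are 95% Wilson intervals. The share rose from 35.2% to 99.97% for replicate 1 and from 70.4% to 100% for replicate 2.

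Shared sites had similar enrichment in the 2 replicates. Across the 22364 shared sites, Spearman's rho of the fold enrichments was 0.74 and Pearson's r of the log2 folds was 0.79. These are correlations across sites, which are not independent replicates. The fold was higher in replicate 1 at 61.6% of the shared sites, and the median log2 ratio of replicate 1 to replicate 2 was 0.14, with an SD of 0.48. The fold adds 1 to pileup and background, which lowers it more where the background is lower. The median background over all peaks was 4.30 in replicate 1 and 2.98 in replicate 2. The shift of 0.14 therefore does not by itself show higher enrichment in replicate 1. The folds lay within 2-fold of each other at 95.1% of the sites. In the strongest decile of shared sites, ranked by the lower of the 2 folds, the SD of the log2 ratio was 0.34, and in the weakest decile it was 0.70. Counting error of the 2 ChIP pileups alone gives 0.21 and 0.44. Counting error of the backgrounds, which also enter the folds, is not included in these values. Ranking by the lower fold also places pairs with 1 low and 1 high fold in the weak deciles, so part of the contrast is built in. The 100 sites of highest fold in each replicate had 49 in common, where independent lists would share 0.447. The 1000 highest had 642 in common, where independent lists would share 44.7.

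**Figure D3:**
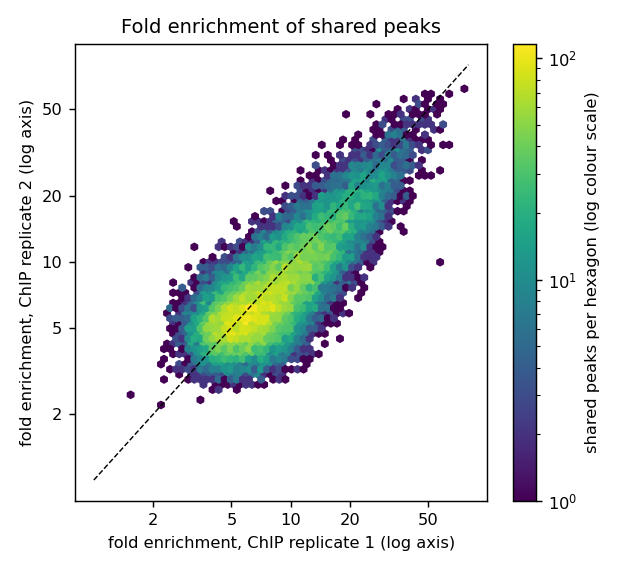
Fold enrichment of the 22364 shared sites in ChIP replicate 1 (x axis) and replicate 2 (y axis), both on log axes; colour gives the number of sites per hexagon and the dashed line marks equal folds. Sites followed the line with Spearman's rho of 0.74 and spread most where the lower of the 2 folds was low.

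The strongest shared sites lay on 12 of the 20 chromosomes and stood far above the typical site. The 20 with the highest lower-of-2 fold had mean folds between 45.5 and 69.2, and their summits differed by at most 47 bp between replicates. The first was on chromosome 9 at 6967190 to 6968056, with a fold enrichment of 69.2 ± 10.0 (SD, n = 2). It rested on 391 fragments (95% exact Poisson interval 353 to 432) in replicate 1 and on 339 (304 to 377) in replicate 2, the summits being at 6967565 and 6967591. Another site on chromosome 9, at 1568482 to 1569382, reached 61.9 ± 5.12 (SD, n = 2), with 309 and 240 fragments. One more site on that chromosome, at 32341219 to 32341935, reached 53.9 ± 3.63 (SD, n = 2). On chromosome 14, the site at 13786523 to 13787332 had a fold of 57.2 ± 1.51 (SD, n = 2), with 308 and 226 fragments.

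Chromosome 19 also held 3 of these 20 sites. The site at 48891805 to 48892438 had a fold of 53.4 ± 1.28 (SD, n = 2), that at 45041775 to 45043332 had 52.4 ± 8.13, and that at 39130630 to 39132159 had 51.5 ± 2.58. The site on chromosome 16 at 25636560 to 25637644 reached 56.0 ± 5.40 (SD, n = 2), and that on chromosome 1 at 50871501 to 50872281 reached 52.9 ± 2.09. Chromosome 4 held a site of 55.8 ± 6.63 at 8858243 to 8858972 and one of 49.9 ± 1.49 at 3158964 to 3159793. The remaining sites were 3 on chromosome 18, 2 on chromosome 15 and 1 each on chromosomes 8, 12, 13 and 20. The fold was higher in replicate 1 at 13 of the 20 sites, and the SD between replicates averaged 3.61. Many neighbouring ranks differed by less than this spread. Coordinates are 1-based positions on the assembly used by the authors, whose name is not given in the sources used here. Genes next to the sites were not analysed here, because no genome or annotation of that assembly was used.

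**Figure D4:**
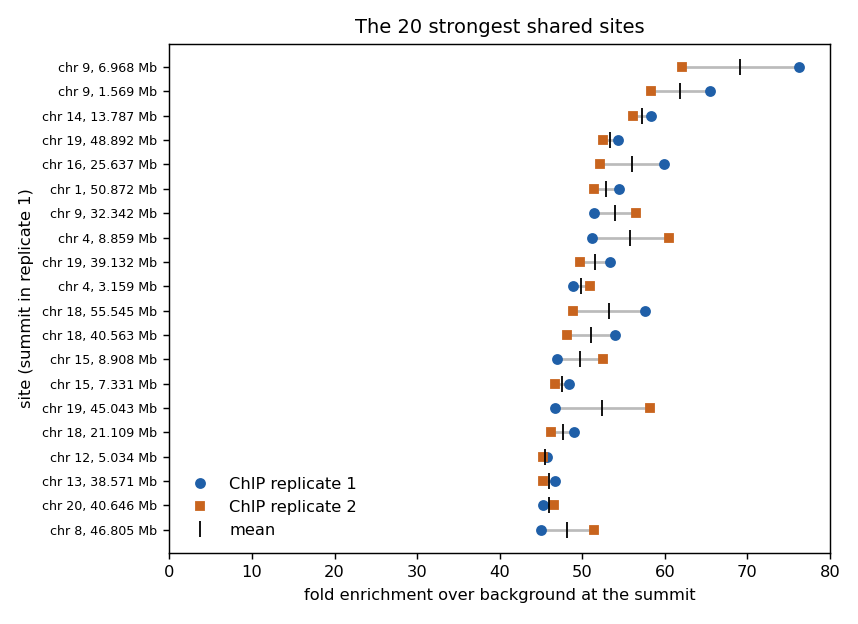
Fold enrichment over background (x axis) of the 20 shared sites with the highest lower-of-2 fold (y axis, chromosome and summit position in replicate 1); circles are ChIP replicate 1, squares replicate 2 and ticks their mean. All mean folds lie between 45.5 and 69.2.

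Shared sites were denser per Mb towards the chromosome ends. The outer 25% at each end of the 20 chromosomes held 37.5 ± 5.56 shared sites per Mb (SD over chromosomes, n = 20), and the central 50% held 10.0 ± 7.67. The difference was 27.5 ± 8.96 sites per Mb (two-sided sign-flip permutation test, 100000 resamples, p = 2e-05), and the outer parts were denser on 19 of the 20 chromosomes. The ratio of outer to inner density reached 11.4 on chromosome 4 and 8.33 on chromosome 10, and was 2.32 on chromosome 8. The exception was chromosome 13, with 32.2 sites per Mb in its outer parts and 38.4 in its central part. Its longest stretch without a shared site, 5477539 to 9773607, lay within an outer part. Each replicate alone gave denser outer parts on 19 chromosomes, with means of 52.2 and 13.9 peaks per Mb in replicate 1 and of 42.9 and 11.3 in replicate 2. These densities do not allow for the density of genes or for how much of the sequence reads can be aligned to. The test therefore does not show a preference of the protein itself for chromosome ends.

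Chromosome 13 had the highest density of shared sites, 35.3 per Mb, followed by chromosome 11 with 31.5 and chromosome 17 with 31.2. Chromosome 18 had the lowest, with 17.7, and chromosome 20 had 18.4. Chromosome 13 ranked first in both replicates, with 49.4 peaks per Mb in replicate 1 and 39.9 in replicate 2. The mean over chromosomes was 23.8 ± 4.99 shared sites per Mb (SD, n = 20). The strength of the sites varied little between chromosomes, since the median lower-of-2 fold lay between 6.11 and 6.58 on all 20. Chromosome lengths were taken as the end of the last peak.

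In windows of 1 Mb the median was 13 shared sites. The 160 windows with at least 50 shared sites made up 17.1% of the 936 complete windows and held 45.5% of the sites in them. The densest was 3 to 4 Mb on chromosome 6, with 91 shared sites. It was followed by 4 to 5 Mb on chromosome 11 with 88, and by 34 to 35 Mb on chromosome 13 and 3 to 4 Mb on chromosome 4, each with 85. At the other end, 54 windows held no shared site, and 33 held no peak in either replicate. The longest stretch without a shared site spanned 4.30 Mb on chromosome 13, between summits at 5477539 and 9773607. Chromosome 6 had a stretch of 3.70 Mb and chromosome 2 one of 3.41 Mb.

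**Figure D5:**
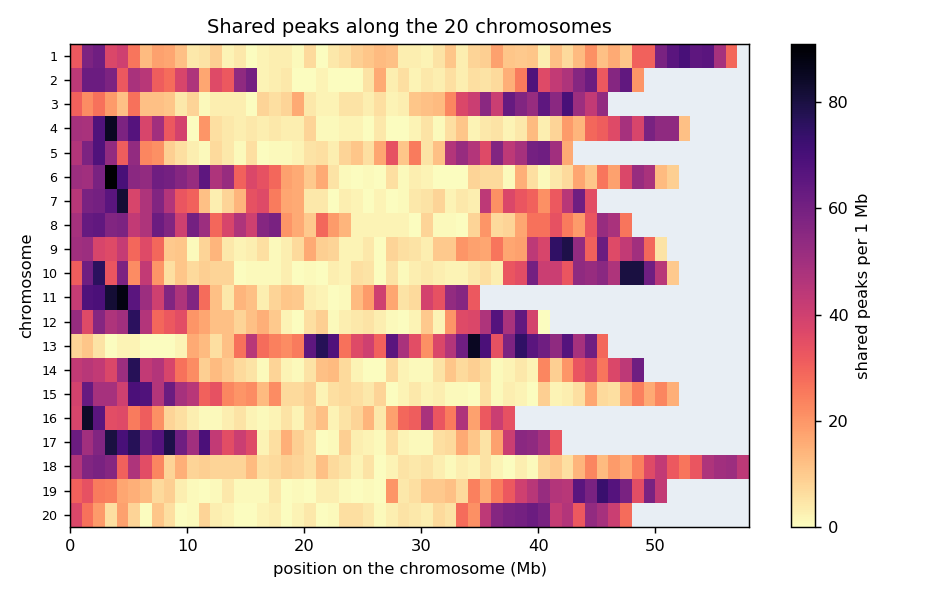
Shared sites per 1 Mb window (colour) along the 20 chromosomes (y axis) by position in Mb (x axis); grey lies beyond the last peak of a chromosome. The densest window, 3 to 4 Mb on chromosome 6, holds 91 shared sites, and chromosome 13 alone was denser in its central 50% than in its outer parts.

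Shared sites also lay close to each other more often than regional density gives. A second shared site within 2 kb was present for 30.0% of the shared sites. Placement at random within 500 kb gave 16.0% on average and at most 16.97% in 1000 draws (one-sided permutation test, p = 0.001, the smallest these draws can give). Runs of sites spaced by at most 2 kb numbered 2986, of which 122 held at least 4 sites. The longest held 9 shared sites in 10.3 kb on chromosome 17, at 8630433 to 8640688, with lower-of-2 folds from 4.20 to 25.9. A run of 8 lay on chromosome 8 at 45698234 to 45705685, and a run of 7 on chromosome 6 at 7192430 to 7200755. On chromosome 13, a run of 5 at 42031666 to 42037041 had a median lower-of-2 fold of 14.5. The random placements do not keep the spacing of genes.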

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

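The limit of 20 on the background, the comparison of these peaks with replicate 1 and the conversion of their pileups were chosen after the peaks had been seen.

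Replicate 2 held 106 peaks whose recovered background was over 20 fragments, against 5 in replicate 1. They drew attention because the level of the background itself was not compared between replicates. The 106 peaks formed 81 loci, the largest with 11 peaks in 9.60 kb on chromosome 12, at 39184641 to 39194240. Their median fold was 1.67, with a range of 1.301 to 2.84. All 5 in replicate 1 overlapped a replicate 2 peak.

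Binding of the assayed protein at these loci stays open: 2.83% of the 106 peaks (95% Wilson interval 0.967 to 7.99) overlapped a replicate 1 peak. The replicate 1 background at these loci is not known, so this low share cannot decide. At the median background of all replicate 1 peaks, 4.30, their median fold gives 7.85 fragments. This is under its smallest called pileup of 12, so such sites would be missed. At a high background they could be called, since the 5 replicate 1 peaks over 20 had a median background of 37.0 and a median fold of 2.34. Removal of duplicate reads is a candidate cause, since it limits pileups to 2 fragment lengths and the highest input pileup of replicate 2 was 380 against a limit of 382. Where the input exceeded 50% of the limit (72 peaks), conversion to reads before such removal lowered the median ratio of ChIP to scaled input from 1.61 to 1.31 and left 50.2% of the excess over 1 (bootstrap interval 30.9 to 68.9), so this stays open for them. The other 34 peaks went from 1.97 to 1.96. This does not decide the matter for them, because the conversion takes the limit as 2 fragment lengths at every locus. ChIP and input both held at a lower local limit would give a ratio of 2.01. Removal of duplicates therefore stays open for peaks up to that ratio. Of all 106 peaks, 86 had a fold of at most 2.01. Among the 34 peaks, the upper quartile of the converted ratio was 2.33. Ratios above 2.01 are more than such a limit alone gives, but their counting error was not assessed. Many-copy sequence or DNA of another source in the replicate 2 libraries stays open for all 106 peaks, because their sequences were not analysed here.

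Unplaced scaffolds, which the comparisons along chromosomes leave out, carried 182 peaks in replicate 1 and 152 peaks in replicate 2. Of these, 73.6% and 90.1% overlapped a peak of the other replicate, where peaks on chromosomes gave 72.0% and 89.8%.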

How the results depend on the processing

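The alternatives for the number of shared sites, the density along chromosomes and the neighbours within 2 kb, the removal of peaks with a background over 20 and the placement within 500 kb were chosen after seeing the data. The replicate overlap, the difference between outer and central density and the share with a neighbour kept their direction and passed their test in all 22 alternatives tested, and the overlap of replicate 1 ranged from 66.3% (summits within 100 bp) to 80.6% (5000 strongest peaks of each list). With a −log10 q of at least 10, the shared sites fell to 14706 and Spearman's rho of the folds was 0.714. With the 5000 strongest peaks they fell to 4029, with a rho of 0.593. Both alternatives use fewer peaks by construction. Reciprocal overlap of 50% gave a rho of 0.749, and −log10 q in place of fold gave 0.815. The cause of the changes in rho was not tested. All peaks of replicate 1 alone gave an outer minus central density of 38.4 per Mb and a neighbour share of 37.2%, against 21.3% at random placement. All peaks of replicate 2 alone gave 31.6 per Mb and 34.1%, against 17.9% at random placement. The fewer sites of −log10 q at least 10 gave 18.1 per Mb and 22.7%, against 10.9% with a neighbour at random placement. The 5000 strongest peaks gave 4.88 per Mb and 10.4%, against 3.37% at random placement. A strong site's fold in 1 replicate lies within 1 SD of the mean of 2 by construction, so leaving out a replicate says nothing about it. No paired analysis was possible because the inputs enter only through the authors' peak calling, so ChIP and input could not be fitted together. Placement around gene starts and every setting for location, motifs, 6-mers, bound genes and gene lists, fixed before the data were examined, were not run, as they need the genome or annotation of the assembly used. Replicate 1 sites without a counterpart had a median of 23 fragments and those with one had 42, and whether depth limits their recovery was not tested.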

Other observations

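The test of high background as a source of extra peaks, the thresholds of −log10 p other than the weakest p, and the single discordant sites were chosen after their values had been seen.

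Single strong sites differed between the replicates. Of the 1899 shared sites with a fold over 20 in either replicate, 111 were over 2-fold apart, and some of the most extreme are given here. Among the shared sites with a fold over 20 in either replicate, the pair with the largest ratio of folds was on chromosome 7 at 44132028 to 44133685, with a fold of 55.9 on 399 fragments in replicate 1 and of 10.2 on 43 fragments in replicate 2. Its summits lay 261 bp apart, so the folds were read at different positions and the pair is not shared when summits must lie within 100 bp. The next pair, on chromosome 13 at 33085833 to 33086392, had folds of 22.4 and 6.78 at summits 112 bp apart. It had 103 and 53 fragments over backgrounds of 3.63 and 6.96. A site on chromosome 5 at 33745550 to 33746162 had folds of 23.5 and 7.57 at summits 3 bp apart. Its 98 and 48 fragments lay over backgrounds of 3.20 and 5.47, so pileup and background both differed. In the other direction, a site on chromosome 13 at 39560538 to 39561125 had folds of 7.78 and 20.8, with 89 and 72 fragments over backgrounds of 10.6 and 2.51. A site on chromosome 4 at 6909711 to 6910273 had folds of 13.98 and 34.5, with 136 and 120 fragments over backgrounds of 8.80 and 2.51. At these last 2 sites the pileups were similar and the backgrounds differed.

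The ratio of replicate 1 to replicate 2 pileup, each after subtraction of its background, fell at the strongest sites. Its median log2 value was 0.61 in 3843 pairs with a summed pileup of 75 to 100 and 0.39 in 243 pairs above 300, a fall of 0.22 (bootstrap interval 0.19 to 0.25). Selection of pairs by their pileup gave a fall of 0.0025 in simulated pairs with 1 ratio and Poisson noise only. This argues against selection acting on counting noise of the pileups. In the strongest decile the SD of the log2 fold ratio was 0.34, against 0.21 from counting error of the ChIP pileups alone. The 0.21 leaves out counting error of the backgrounds, and the fold is another measure than the ratio used here. Whether the replicates differed by more than counting noise is therefore not settled. Selection acting on variation other than counting noise of the pileups was not simulated and stays open. Removal of duplicate reads may contribute, since the highest pileups reached 89.9% and 88.7% of 2 fragment lengths. Conversion to reads before removal left a fall of 0.17 (0.14 to 0.22). This argues against removal as the whole cause if read starts are spread evenly over the positions of both strands. The interval does not cover that assumption, and clustered read starts were not tested. A difference between the immunoprecipitations was not tested.

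Replicate 1 had 5588 more peaks than replicate 2. Peaks of high background cannot be the source, because replicate 1 had fewer of them (a difference of −101). More reads and longer fragments in replicate 1 may account for part of the excess, but whether they account for all of it stays open, as does higher enrichment in replicate 1. With pileups and backgrounds scaled to the background of replicate 2, 30785 replicate 1 peaks passed the weakest p of the replicate 2 list against 31070 unscaled. The scaled count was 121% of the replicate 2 number, outside the margin of 10% fixed beforehand for reads and fragment length as the cause. Since nearly every peak passes that p with or without scaling, this count decides nothing. At higher thresholds the scaling lowered the ratio of replicate 1 to replicate 2 peak numbers from 128% to 104% at a −log10 p of at least 10, from 146% to 111% at 20, from 170% to 115% at 40 and from 212% to 121% at 80.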
